A study of Mus musculus with 6 samples.

How the data were processed

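Messenger RNA was sequenced on the BGISEQ-500 platform from mouse first mandibular molars at postnatal day 4. The 6 libraries fall into 2 groups of 3. One group carried K14-Cre, a recombinase driven by the keratin 14 promoter and so active in epithelium, together with 2 floxed alleles of Wnt10a. The other group held littermates with the floxed alleles and no Cre. Groups and replicate numbers were taken from the sample labels. The labels do not state whether a library came from 1 animal or from a pool, so p-values measure the spread between these samples.

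The authors' deposited table gives FPKM (fragments per kilobase of transcript scaled to the mapped total) for each library, with 2 decimals, per the file headers. Reads were aligned with Bowtie2 to mm10, per the submitters' processing notes. The version of the aligner, the tool that computed FPKM and the annotation release are not given in the sources used here. Per the file headers, the same table holds the authors' log2 ratio of knockout to control, their p-value and q-value, and the length of the longest transcript of each gene. The authors' test is not given in the sources used here. The table has 17582 rows, keyed by Entrez gene number, and no row is at 0 in all libraries. The symbols of 25 genes appear as dates in the table and were restored from the gene numbers. FPKM divides by transcript length and by each library's total, so a few abundant transcripts lower the values of all other genes. Amelx alone took between 30.6% and 35.9% of the summed FPKM of a library. Its share of reads, which bears on the mapped total, was smaller, between 13.0% and 15.7% of the reads rebuilt as described below.

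Sequencing depth was estimated from the steps between low FPKM values, since 1 read is worth a fixed FPKM at a given transcript length. With 30 bases subtracted from the length, the estimates were 18410000, 18060000 and 18420000 reads for knockout libraries 1, 2 and 3, and 17850000, 17900000 and 18330000 for control libraries 1, 2 and 3. At these depths between 85.2% and 89.1% of the low values lay within 0.15 of a whole read, where 30% would by chance. Reads per gene were rebuilt from FPKM, length and these depths for descriptive use, for one alternative and for a test of pooled reads. The intervals printed come from the spread between libraries.

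The planned main test was a count model. Because the values are FPKM, the fallback fixed in advance was used, limma-trend (limma 3.58.1 in R 4.3.3) on log2(FPKM + 1) with group as the only term. Genes at 1 FPKM or more in at least 3 libraries were tested, which left 11934. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. In data simulated from these libraries, with 200 of the 11934 genes changed, the test recovered 7.6% of genes changed 1.25-fold, 81% of those changed 1.5-fold and 96.8% of those changed 2-fold. False calls per run averaged 2.6, 10.3 and 14. The simulated genes varied independently, while genes of real libraries can vary together. With fewer changed genes the adjusted threshold is also stricter, so these shares may overstate what the test recovers here.

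Before the data were examined, 29 gene lists with 396 entries were fixed, of which 374 were found in the table. They cover Wnt ligands, feedback targets of the Wnt/beta-catenin pathway, Wnt receptors and antagonists, the Hedgehog, BMP and TGF-beta, FGF, Notch and ectodysplasin pathways, the cell cycle, the cell types of the tooth, other cell types that a dissected molar can carry, and signs of RNA handling. The 25 lists with at least 3 tested members were tested with camera, two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. A list of sex-linked genes served as a check of the libraries and was not tested. The camera test was run with limma's default variance and with a variance trended on mean level. The design named neither, and the default was settled on after both results had been seen.

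The rule for named genes, also fixed in advance, took Wnt10a, up to 12 genes per direction past the threshold, up to 4 members of each list past the threshold or otherwise its 3 most abundant, and genes that check the libraries. If no gene passed, the 5 genes per direction with the smallest p were to be given. Since the targeted gene alone passed, this last step was applied with Wnt10a set aside, a reading settled after the values were seen. Gene positions come from GENCODE release M21 on GRCm38, the assembly also called mm10. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

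Alternatives fixed in advance were a pseudocount of 0.1, no filter on low values, replicate number as a block, each library left out in turn, and an inter-gene correlation estimated per list. Added after the data were seen were a filter at 5 FPKM, median-ratio scaling between libraries, removal of each library's trend with transcript length (loess, span 0.5) alone or with another choice, limma-voom on the rebuilt reads, and, for the lists, the trended variance, the pseudocount and the missing filter.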

Results

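First mandibular molars of mice at postnatal day 4 were profiled in 3 libraries with epithelial deletion of Wnt10a and 3 libraries from littermate controls. Wnt10a encodes a secreted Wnt ligand. The comparison asks which transcripts of the molar differ when Wnt10a is targeted for deletion in its epithelium. Estimated depth was between 17850000 and 18420000 reads per library, and between 11774 and 12025 genes reached 1 FPKM. Enamel matrix transcripts dominated both groups. Amelx, which encodes amelogenin, the main protein of forming enamel, stood at 188200 ± 18660 FPKM in the knockout and 186200 ± 15840 FPKM in the control (SD, n = 3 each). It took between 13.0% and 15.7% of the rebuilt reads of a library.

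Wnt10a itself was lower in every knockout library than in every control library. Its level was 19.1 ± 0.961 FPKM in the knockout and 34.0 ± 2.47 FPKM in the control (SD, n = 3 each), a change of the means of -43.7%. The knockout libraries held 19.39, 19.94 and 18.07 FPKM, and the control libraries 33.61, 36.59 and 31.68 FPKM. The log2 fold change was -0.795 (SE 0.077, 95% interval -0.963 to -0.626), with a limma adjusted p of 0.00609. These levels correspond to between 643 and 696 rebuilt reads per knockout library and between 1122 and 1265 per control library. The gene (Entrez 22409) lies on the plus strand of chromosome 1, from 74791516 to 74804179 in mm10, and has 4 exons in the annotation. The labels do not give the deleted exons, and the values do not separate epithelial from mesenchymal transcripts or reads by exon. Without a filter on low values, the adjusted p of Wnt10a was 0.106.

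**Figure D1:**
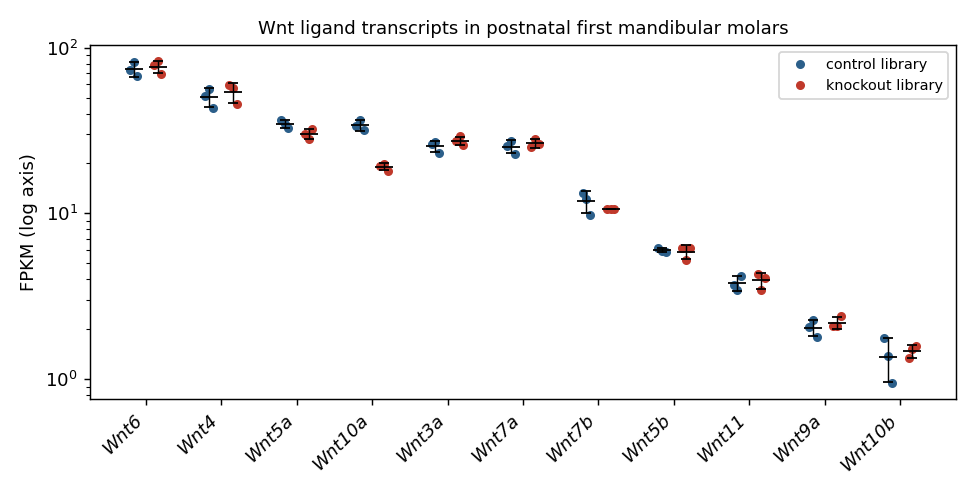
FPKM on a log axis of the 11 tested Wnt ligands in control (blue) and knockout (red) libraries; points are libraries, and black bars give the mean and SD of 3 libraries. Wnt10a lies between 18.07 and 19.94 FPKM in the knockout and between 31.68 and 36.59 FPKM in the control, while the other ligands differ by less on the log2 scale, from -0.19 to 0.11.

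Wnt10a was the one gene of 11934 past the threshold by limma-trend. No gene was higher past it, and no called gene changed 2-fold or more. At an unadjusted p under 0.05 there were 680 genes, 357 higher and 323 lower, where chance gives 597 on average. Regroupings of the 6 libraries that mixed the genotypes gave between 67 and 1853 such genes. The distance of 680 from 597 lies within that spread. The groups did not overlap for 1211 genes, or 10.1%, and chance gives 10% for 3 against 3. On the log2(FPKM + 1) scale the 95% interval lay within a change of 1 in either direction for 11894 genes, or 99.7%. This scale compresses low genes, so a 2-fold change in FPKM is not excluded for genes near the filter, such as Arhgap36, whose means differed 2.165-fold. The median SE was 0.091. The count was 0 without a filter on low values, 2 with limma-voom on rebuilt reads, 3 with a filter at 5 FPKM, 3 without control 2 and 6 without knockout 3.

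The other Wnt ligands of the molar kept levels near those of the control. Of 11 tested ligands, 1 fell, Wnt10a, both over all genes and adjusted over the list alone. The fold changes of the other 10 lay between -0.19 and 0.11 on the log2 scale, with 95% intervals between -0.358 and 0.363 and a lowest adjusted p of 0.869. Wnt6, whose annotated end lies 6194 bases before the start of Wnt10a on the same strand, was the most abundant ligand, at 76.7 ± 6.67 FPKM in the knockout and 74.2 ± 7.76 FPKM in the control. Wnt4 stood at 54.0 ± 7.38 and 50.3 ± 6.40 FPKM, a log2 fold change of 0.10 (SE 0.113, limma adjusted p = 0.924). Both were named after their values were seen. The list as a whole had a median of 0.05 and a mean of -0.06, which differ in sign, and camera gave it an adjusted p of 0.651 in the lower direction.

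Feedback targets of Wnt/beta-catenin signalling, genes that the pathway switches on in many tissues, did not pass the test. None of 13 tested members passed over all genes or adjusted over the list alone, and the list median was -0.07 (camera adjusted p = 0.300). Wif1, a secreted Wnt inhibitor, was at 132 ± 2.08 FPKM in the knockout and 138 ± 5.34 FPKM in the control. Tnfrsf19 was at 42.9 ± 0.244 and 43.3 ± 1.94 FPKM, and Apcdd1, an inhibitor of Wnt receptors, at 40.0 ± 2.54 and 36.9 ± 2.41 FPKM. Axin2 and Lef1, named after their values were seen, had log2 fold changes of -0.003 (SE 0.089) and -0.21 (SE 0.112). Among 24 Wnt receptors and secreted antagonists the median was -0.04 (camera adjusted p = 0.532). Sostdc1, an antagonist of Wnt and BMP signals in teeth, was at 109 ± 6.14 FPKM in the knockout and 97.7 ± 12.03 FPKM in the control.

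Other signalling pathways of tooth development gave no call. The Hedgehog list (11 tested) had a median of -0.09 and an adjusted p of 0.606. Shh, the ligand made by dental epithelium, was at 51.4 ± 10.5 FPKM in the knockout and 45.2 ± 9.08 FPKM in the control, and its target Gli1 at 87.2 ± 6.41 and 79.7 ± 9.91 FPKM. The BMP and TGF-beta list (19 tested) had a median of -0.02 and an adjusted p of 0.783, with Id1, a BMP target, at 74.0 ± 8.33 and 69.6 ± 4.72 FPKM. The FGF list (9 tested) had a median of -0.04 and an adjusted p of 0.912. Its receptor Fgfr1 was at 224 ± 16.3 and 236 ± 4.95 FPKM. The Notch list (14 tested) had a median of -0.04 and an adjusted p of 0.606, and the ectodysplasin list (6 tested) a median of -0.02 and an adjusted p of 0.912. The cell cycle list (23 tested) had a median of -0.03 and an adjusted p of 0.663, and Pcna, a replication factor, was at 30.1 ± 3.46 and 28.3 ± 1.27 FPKM. None of the 130 tested members of these pathway and cell cycle lists passed over all genes, apart from Wnt10a.

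Below the threshold, 10 further genes are given as those with the smallest p in each direction. Higher in the knockout were Uchl1, a neuronal ubiquitin hydrolase, at 35.1 ± 3.35 against 22.8 ± 1.33 FPKM (log2 fold change 0.60, SE 0.084, limma adjusted p = 0.0735), Npff (0.69, adjusted p = 0.197), Arhgap36 (0.64, adjusted p = 0.208), Crhr1 (0.44, adjusted p = 0.221) and Rpl36 (0.40, adjusted p = 0.197). Rpl36 has processed pseudogenes that can share its reads, and after removal of the length trend its log2 fold change was 0.24 (adjusted p = 0.357). Lower were Itpr1, a calcium release channel of the endoplasmic reticulum, at 11.2 ± 0.607 against 18.5 ± 2.21 FPKM (-0.67, SE 0.091, limma adjusted p = 0.0735), Ibsp (-0.48, adjusted p = 0.144), Olfm1 (-0.39, adjusted p = 0.242), Lhfpl2 (-0.37, adjusted p = 0.242) and Ndrg1 (-0.33, adjusted p = 0.242). Each of the 10 had groups that did not overlap, which a choice by the smallest p makes likely. With a filter at 5 FPKM, Uchl1 and Itpr1 both had an adjusted p of 0.0311. Itpr1 also passed with limma-voom on rebuilt reads (adjusted p = 0.016) and without control 2 (limma adjusted p = 0.04). Uchl1 passed without knockout 3 (limma adjusted p = 0.0118). Control 2 held the control value of Itpr1 nearest the knockouts (16.63 FPKM). Knockout 3 held the knockout value of Uchl1 nearest the controls (31.42 FPKM). Smaller p-values after these 2 omissions are therefore no support for a change. Neither gene passed without a filter on low values.

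Among the cell types of the tooth, genes of odontoblasts, the cells that make dentin, were lower as a list with the preset correlation. The odontoblast and dentin list had 14 tested members, 12 of them below 0, a median of -0.12 and a camera adjusted p of 0.0292. With an estimated correlation the adjusted p was 0.880. Every split of the 6 libraries into 3 and 3 passed at least as many lists as the real one. No member passed over all genes or adjusted over the list alone. Col1a1, a chain of type I collagen, was at 5129 ± 1350 FPKM in the knockout and 6070 ± 771.6 FPKM in the control, and Dspp, the precursor of the main dentin phosphoprotein, at 714 ± 124 and 773 ± 61.8 FPKM. Dspp was named after its values were seen. Col1a1 was at 4042.67 and 4703.32 FPKM in knockouts 1 and 2, and at 6639.76 FPKM in knockout 3, the knockout library with the most muscle transcripts. Controls 1, 2 and 3 held 5777.44, 5488.17 and 6945.61 FPKM. Col1a1, Col1a2, Sparc, Sp7 and Alpl of this list are also made by osteoblasts, and the lists for bone, osteoclast, cartilage and dental follicle had medians of -0.13, -0.37, -0.25 and -0.13. The adjusted p of the list was 0.439 without knockout 1, 0.0654 without knockout 2, 0.188 without control 3 and 0.000199 without knockout 3. It was 0.0919 after removal of the trend with transcript length, where the list median was -0.087. It was 0.0955 with median-ratio scaling, which moved the fold changes of all genes by a median of -0.014.

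Ameloblast and epithelial genes gave no call. Of 13 secretory-stage genes none passed, with a median of -0.04 (camera adjusted p = 0.554). Ambn, an enamel matrix protein, was at 38370 ± 2324 FPKM in the knockout and 37880 ± 2816 FPKM in the control, and Enam at 3279 ± 124 and 3382 ± 78.4 FPKM. The maturation-stage list (8 tested) had a median of -0.08 and an adjusted p of 0.159, with Amtn at 54.8 ± 10.3 and 75.6 ± 33.2 FPKM. Amtn was at 113.54 FPKM in control 3 and at 61.37 and 51.76 FPKM in controls 1 and 2. The dental epithelium list (14 tested) had a median of 0.06 in the higher direction (adjusted p = 0.460). Krt14, whose promoter drives the Cre, was at 932 ± 100 FPKM in the knockout and 853 ± 93.8 FPKM in the control, and Krt5, its partner keratin, at 1109 ± 68.8 and 1110 ± 150 FPKM. The dental papilla mesenchyme list (15 tested) had a median of -0.02 (adjusted p = 0.554), with Msx2 at 84.0 ± 3.84 and 84.0 ± 3.09 FPKM. The dental follicle and periodontal ligament list (10 tested) had a median of -0.13 (adjusted p = 0.0730). Its member Tnn fell adjusted over the list alone (0.653 ± 0.155 against 1.45 ± 0.367 FPKM, adjusted p = 0.0105), and over all genes its adjusted p was 0.460. Tnn met the filter of 1 FPKM only through the controls (1.87, 1.29 and 1.19 FPKM), and such a selection near the filter favours a fall. The knockouts held 0.48, 0.70 and 0.78 FPKM. Single libraries moved these lists. Without knockout 3 the follicle list had an adjusted p of 0.00011 and the maturation-stage list one of 0.0364. The follicle list had 0.870 without control 3, and the maturation-stage list 0.697 without control 3 and 0.0101 without control 1. With limma-voom on rebuilt reads the follicle list was at 0.0428.

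**Figure D2:**
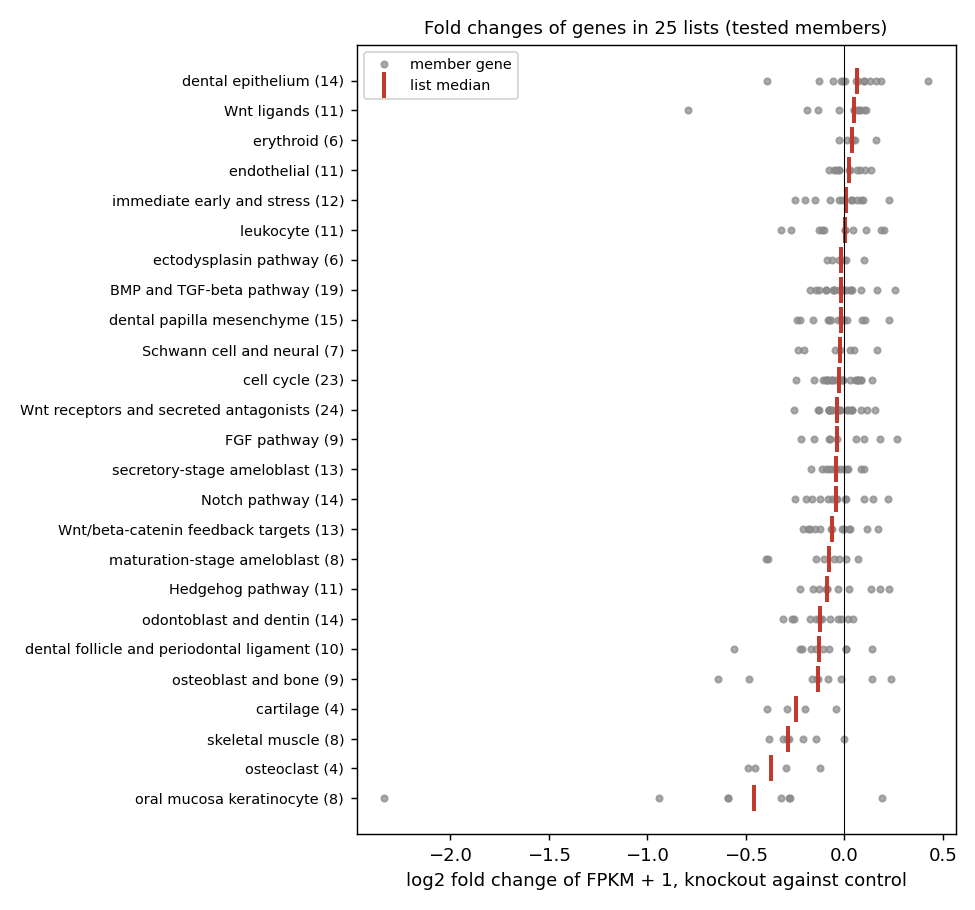
Log2 fold changes of FPKM + 1, knockout against control, for the tested members of 25 gene lists; grey points are genes, red ticks are list medians, and the number of tested members stands in parentheses. The osteoclast list has a median of -0.37 and the odontoblast and dentin list one of -0.12; the single Wnt ligand far to the left is Wnt10a at -0.795.

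Osteoclast genes were lower as a list with the preset correlation. Osteoclasts resorb bone around erupting teeth. The list had 4 tested members, all below 0, with a median of -0.37 and a camera adjusted p of 0.000526. With an estimated correlation, which was 0.6, the adjusted p was 0.663. Each of the 10 splits of the 6 libraries into 3 and 3 passed at least 2 lists with the preset correlation. The real one passed 2, and the highest other 16. Without a filter on low values all 10 members entered, and the median was -0.13 (adjusted p = 0.00797). Acp5, the tartrate-resistant acid phosphatase, was at 14.9 ± 2.26 FPKM in the knockout and 20.7 ± 2.202 FPKM in the control. Mmp9 was at 8.62 ± 2.13 and 12.3 ± 0.665 FPKM, and Ctsk, the collagen-degrading cathepsin K, at 35.7 ± 5.48 and 43.8 ± 1.55 FPKM. These 3 passed adjusted over the list alone (adjusted p = 0.00635, 0.00635 and 0.0145) and 0 passed over all genes. Nfatc1 had a log2 fold change of -0.13 (SE 0.129). Knockout 3, which also held more muscle transcripts than the other knockout libraries, lay nearest the controls. Ctsk was at 42.02 FPKM there and at 32.03 and 33.11 FPKM in knockouts 1 and 2, and Mmp9 at 11.02, 7.87 and 6.97 FPKM. Muscle transcripts did not track these genes among the controls. Control 2 had the least Acta1 of all libraries, 2.22 FPKM, but not the lowest control value of Ctsk, Mmp9 or Acp5 (43.25, 12.33 and 22.48 FPKM). The adjusted p of the list was 4.14e-06 without knockout 3, 0.00882 without knockout 1 and 0.0136 without knockout 2. Without knockout 3, Mmp9 passed over all genes (limma adjusted p = 0.0469). That omission removes the values nearest the controls, so a smaller p there is no support for a fall.

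Genes of osteoblasts and bone did not pass as a list. The 9 tested members had a median of -0.13 (camera adjusted p = 0.131). Ibsp, bone sialoprotein, was at 43.8 ± 2.13 FPKM in the knockout and 61.7 ± 4.74 FPKM in the control, and Spp1, osteopontin, at 24.9 ± 9.85 and 37.7 ± 3.52 FPKM. Both fell adjusted over the list alone (adjusted p = 0.000434 and 0.0324) and neither passed over all genes. Spp1 was at 36.22 FPKM in knockout 3, against 19.79 and 18.60 FPKM in knockouts 1 and 2. Without knockout 3 it passed over all genes (log2 fold change -0.93, limma adjusted p = 0.00839). That omission removes the knockout value nearest the controls, so the smaller p is no support for a fall. Bglap, osteocalcin, was at 1853 ± 112 and 1690 ± 255 FPKM. After removal of the length trend the median was -0.09 and the adjusted p of the list 0.00685, and with an estimated correlation as well the adjusted p was 0.746. With the length trend kept, the adjusted p of the list was 0.0101 without control 1 and 0.0364 without knockout 3. It was 0.104 without knockout 1 and 0.389 without knockout 2.

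Markers of other cell types differed between single libraries. Skeletal muscle transcripts were high in knockout 3, control 1 and control 3, where Acta1 stood at 25.39, 23.82 and 22.41 FPKM, against 5.16, 5.29 and 2.22 FPKM in knockout 1, knockout 2 and control 2. The muscle list (8 tested) had a median of -0.29 (adjusted p = 0.606), lower with 1.11e-05 without control 2 and 0.0181 without knockout 3. It turned to the higher direction, with an adjusted p between 0.647 and 0.697, without knockout 1, knockout 2, control 1 or control 3. Oral mucosa keratins were high in control 1, with Krt13 at 94.24 FPKM and Krt4 at 50.35 FPKM, while the other 5 libraries held between 0.41 and 2.76 FPKM of Krt13. That list (8 tested) had a median of -0.46 (adjusted p = 0.0706). Without control 1 it turned to the higher direction (adjusted p = 0.704), and it was lower past the threshold without control 2 (0.000787) or control 3 (0.000458). The cartilage list (4 tested) had a median of -0.25 (adjusted p = 0.0648). Its adjusted p was 0.00148 without knockout 3 and 0.0101 without control 1, against 0.227 without knockout 1 and 0.321 without knockout 2. Leukocyte genes (11 tested, median 0.002, adjusted p = 0.651), endothelial genes (11 tested, 0.02, adjusted p = 0.663), erythroid genes (6 tested, 0.04, adjusted p = 0.716), Schwann cell and neural genes (7 tested, -0.03, adjusted p = 0.532) and immediate early and stress genes (12 tested, 0.009, adjusted p = 0.791) gave no call with all 6 libraries. The hemoglobin transcript Hba-a1 stood at 1106.94 FPKM in control 3 and 941.17 FPKM in knockout 1, against 587.16 and 616.03 FPKM in controls 1 and 2 and 622.47 and 743.75 FPKM in knockouts 2 and 3. Without control 3 the erythroid list was higher past the threshold (adjusted p = 4.96e-08), and so was the leukocyte list (0.0112), which was lower without control 1 (0.0101) or knockout 3 (0.0451). Adipocyte, salivary gland and mitochondrially encoded genes had 0 tested members. The Y-linked Eif2s3y was at 11.55, 9.88 and 14.99 FPKM in knockouts 1, 2 and 3. It was at 21.03, 17.83 and 0.03 FPKM in controls 1, 2 and 3. Ddx3y was at 4.12, 3.08 and 4.91 FPKM in these knockouts and at 8.16, 6.51 and 0.02 FPKM in these controls. The labels do not give the sex of the animals. Y-linked transcripts were near 0 in control 3 alone, so that library held little or no male tissue. Sex make-up thus differed within the control group. It was also uneven between the groups, since all knockout libraries held these transcripts, and its effect was not separated from genotype.

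**Figure D3:**
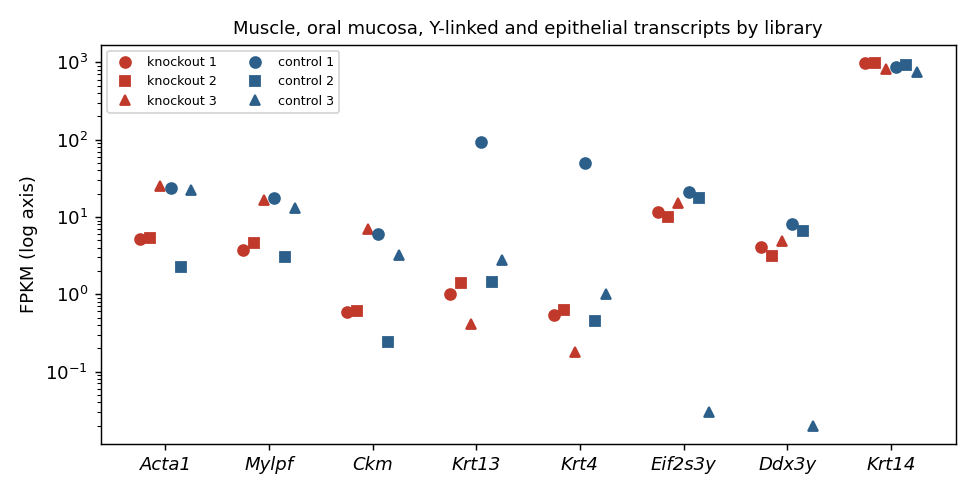
FPKM on a log axis of muscle (Acta1, Mylpf, Ckm), oral mucosa (Krt13, Krt4), Y-linked (Eif2s3y, Ddx3y) and epithelial (Krt14) transcripts in each knockout (red) and control (blue) library, with 1 point per library. Krt13 reaches 94.24 FPKM in control 1, and Eif2s3y stands at 0.03 FPKM in control 3.

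Fold changes went with transcript length. Across the tested genes, which are not independent replicates, Spearman's rho between log2 fold change and length was -0.44. The median fold change was 0.11 for the 796 genes up to 1000 bases long and -0.06 for the 2775 genes over 4500 bases. Knockout 1 and control 1 departed most, with correlations of their deviations with length of -0.51 and 0.44. The other libraries lay between -0.10 and 0.16. The 81 ribosomal protein genes, which are short, had a median of 0.13, and 0.02 after removal of the length trend. Wnt10a had a log2 fold change of -0.83 after that removal (limma adjusted p = 0.000768).

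**Figure D4:**
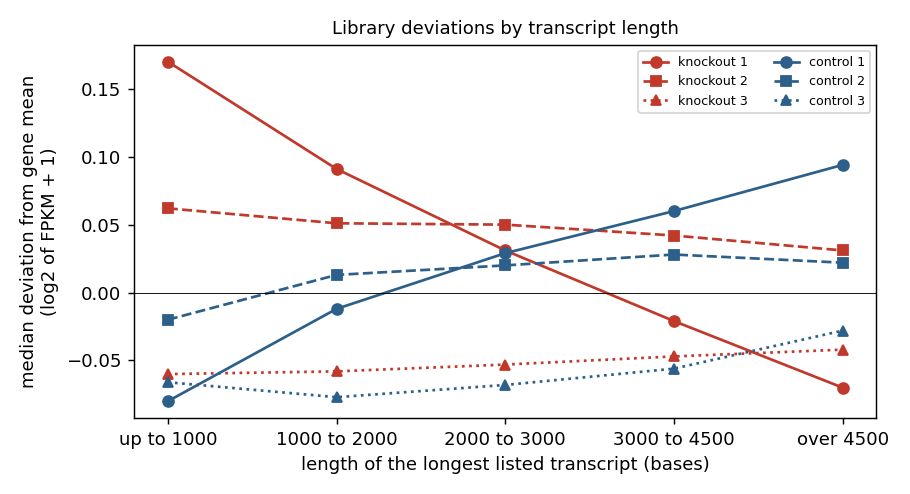
Median deviation of each library from the gene means, in log2 of FPKM + 1, for tested genes in 5 bins of transcript length in bases; lines are knockout (red) and control (blue) libraries. Knockout 1 goes from 0.17 to -0.07 and control 1 from -0.08 to 0.09 between the shortest and the longest bin.

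The authors' deposited table lists many more genes as different. In the authors' deposited table, 4058 of 16662 genes with a q value lie under 0.05, 1703 higher and 2355 lower in the knockout. The median size of the log2 ratio of these genes in the authors' deposited table is 0.17, and 324 have a ratio of 2-fold or more. The groups do not overlap for 1135 of the 4058 genes of the authors' deposited table, or 28.0%. Chance gives 10% for genes not chosen by their q, so it is no reference for this share. Wnt10a has a log2 ratio of -0.83 and a q of 9.04e-96 in the authors' deposited table, rank 22 by q. Amelx, with a log2 ratio of 0.02, has a q of 2.42e-141 in the authors' deposited table, and Wnt4, with 0.10, a q of 2.2e-06.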

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

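The filter at 5 FPKM, the scaling, the length trend, the rebuilt reads and, for lists, the trended variance, pseudocount and missing filter were chosen after seeing the data. Wnt10a stayed below 0 in 14 settings, between -0.842 and -0.741, with an adjusted p of at most 0.0463 wherever a filter was used. Without a filter it kept -0.795 at an adjusted p of 0.106, and the count of genes was 0, with 0 lower. More low genes are then tested, and they also enter the variance fit. Their number alone does not account for the rise, since the unadjusted limma p with the filter was 5.101e-07 and the table has 17582 rows. The part played by the variance fit was not tested. A filter at 5 FPKM gave 3 genes, 1 higher and 2 lower (Uchl1, Itpr1, Wnt10a), and limma-voom on rebuilt reads gave 2, both lower (Itpr1, Wnt10a). Leaving out each library gave between 1 and 6 genes, with between 0 and 3 higher and between 1 and 3 lower. The count was 6 without knockout 3 and 3 without control 2. Replicate number as a block gave 8 genes, 4 higher and 4 lower, among them Itpr1, Uchl1 and Npff (limma adjusted p = 0.0453, 0.0453 and 0.0454). Libraries of the same number had correlations of deviations of -0.06, 0.17 and 0.39, so the numbers were not taken to pair the samples, and not every library correlated best with its own number, since knockout 1 did so with control 2 (0.30).

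Of 25 lists, 2 passed. With an estimated correlation 0 passed, with an adjusted p of 0.663 for osteoclast and 0.880 for odontoblast and dentin, and 0 when the length trend was also removed (0.955 for both). The trended variance, the missing filter, limma-voom and the replicate block each gave 4 lists, and the length trend removed with the replicate block gave 8. A pseudocount of 0.1 and median-ratio scaling each gave 1, with the odontoblast and dentin list at 0.0654 and 0.0955, and at 0.0919 after removal of the length trend. Leaving out each library gave between 1 and 8 lists: 1 without knockout 1 or knockout 2, 8 without knockout 3, and 6, 5 and 4 without controls 1, 2 and 3. The odontoblast and dentin list then lay between 0.000199 and 0.439, and the osteoclast list between 4.14e-06 and 0.0136. The leukocyte list, between 0.0101 and 0.647, turned to the higher direction without control 3 (adjusted p = 0.0112). Of 23 lists that did not pass, 8 passed in some setting. The causes of these shifts were not tested. For 101 other named genes, 128 of 1398 pairs of gene and setting had another sign, in 49 genes, and 10 pairs in 5 genes passed the threshold. The planned count-model tests, their scaling factors, voom on deposited counts, the CPM filter and the CPM prior count were not run because the table holds FPKM.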

Other observations

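The tests of the splits for gene lists, of a length trend of single libraries, and of the osteoclast list were chosen only after the result was seen, and so were the genes of the next paragraph.

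The values of 6 further genes, none past the threshold and not tested as a group, are given here. Acta2, smooth muscle actin, was at 19.1 ± 0.818 FPKM in the knockout and 14.2 ± 0.979 FPKM in the control (SD, n = 3 each; log2 fold change 0.40, limma adjusted p = 0.242). Tagln was at 19.9 ± 1.19 and 15.1 ± 0.510 FPKM (0.38, adjusted p = 0.242), and Myl9 at 54.8 ± 3.12 and 44.8 ± 1.99 FPKM (0.28, adjusted p = 0.531). For each of these 3 genes the groups did not overlap, as for 10.1% of all tested genes. Because the 3 were chosen after their values were seen, that share is no reference for them. Ndrg1, Bnip3 and Ndufa4l2, which low oxygen induces in many cells, lay below the control, with log2 fold changes of -0.33, -0.33 and -0.59 (adjusted p = 0.242, 0.607 and 0.242).

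A hypothesis is that transcripts induced by low oxygen may be lower as a class in the knockout. A list of 26 other such genes was written before its values were seen. Camera gave it an unadjusted p of 0.0296 with a median of -0.05, and one of 0.00308 with a median of -0.06 after removal of the length trend. With an estimated correlation, which the prediction had not named, the p was 0.552, so the hypothesis stays open. Gapdh and Aldoa in that list had log2 fold changes of -0.003 and -0.02, and Ldha one of -0.23.

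Other splits of the 6 libraries into 3 and 3 are 10 with the real one, too few for a share under 0.05. The real split gave 1 gene and the highest of the others 12, and 2 of the 10 splits gave as many as the real one. The split with 12 set knockout 1, knockout 2 and control 2 apart, the libraries with 5.16, 5.29 and 2.22 FPKM of Acta1. For lists the real split gave 2 and the highest other 16, and 10 of the 10 splits gave as many. Splits that call several times the real number point to a structure of the libraries other than genotype.

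The osteoclast list was lower in the knockout; the trend with transcript length was argued against as the whole source, since the median was -0.415 after its removal and the list still passed with the preset correlation (adjusted p = 0.00502). Fewer leukocytes of all kinds were argued against as the whole source, since the leukocyte list had a median of 0.002, and of -0.118 after that removal, and lay above the osteoclast list by between 0.186 and 0.455 in the settings with a filter (SD of its members 0.171), though by 0.068 without one. A partial share stays open, as the leukocyte list passed in the lower direction without control 1 (adjusted p = 0.0101) or knockout 3 (0.0451) and in the higher direction without control 3 (0.0112). Less adhering bone in the knockout dissections may contribute. Ifitm5, Sost and Omd had a median of -0.132 with SEs between 0.080 and 0.201. Of the 9 tested members of the bone list, 7 were below 0. Its 2 most abundant members went the other way, Bglap at 0.141 (SE 0.109) and Bglap2 at 0.235 (SE 0.093). After removal of the length trend they were at -0.006 and 0.087. Dissection and an effect of genotype cannot be told apart here, and the call itself is lost with an estimated correlation (adjusted p = 0.663).

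Fold changes were lower for longer transcripts. GC content in its place was argued against by the partial correlation with length given GC content, -0.468 against -0.439 without it. A trend of single libraries stays open: the difference of the mean length correlations, knockout minus control, was -0.402 with an exact permutation p of 0.1, two-sided, the smallest that 3 against 3 can give. The correlations ranged over 0.581 within the knockout and 0.364 within the control, and the nearest libraries of the groups differed little (0.075 and 0.079). Without both libraries numbered 1, rho was -0.144, so a library effect may account for part of the trend, and genotype cannot be told apart from it with these samples.

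The authors' deposited table has 4058 genes at q under 0.05, against 1 here. A candidate explanation is a test without the spread between replicate libraries. A test of pooled rebuilt reads that knows counting error alone called 3478 genes in the real split and between 788 and 5228 in the 9 splits that mix the genotypes, 3 of which had as many as the real one. Of these 9 splits, 8 called more than 1000. The prediction had asked for more than 1000 without saying in how many splits, and with 788 in the lowest it was left open. In the authors' deposited table, the groups do not overlap for 1135 of the 4058 genes. Amelx, whose groups overlap, has a q of 2.42e-141 there, against a limma adjusted p of 0.994 here. These values go with the explanation, but the authors' test is not given in the sources used here.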
